A study of Mus musculus with 19 samples.

How the data were processed

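Hippocampal RNA from 19 mice was hybridised to Agilent whole-genome mouse arrays, 1 array per sample. The labels give 3 groups: wild-type (WT) littermates on vehicle (n = 6), APP/PS1 mice on vehicle (n = 7) and APP/PS1 mice on urolithin A (UA, n = 6). APP/PS1 mice are a transgenic model of amyloid deposition. UA is a metabolite that gut bacteria make from dietary ellagitannins. It was given by gavage in DMSO at 200 mg per kg per day from 6 to 8 months of age, per the labels, and the vehicle groups received DMSO. The group sizes equal the numbers of mice in the series' design text, so each array was taken as 1 mouse.

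The scanner files hold spot intensity from Agilent Feature Extraction version 12.0.3.1 with a protocol for 2-colour expression arrays, per the file headers. The processed green intensity had been background-subtracted and dye-normalized against the red channel within each array, per the file headers, and not normalized between arrays. Per the labels, Cy3 (green) cRNA was made from 200 ng of total RNA. The labels used here describe no red sample, so red values served only as a technical check. Each column of the deposited value table is a score: recomputed from each scanner file, it matched the log10 of the processed green intensity, centred and divided by its SD over all spots of the array, to within 0.00500. The columns' medians ran from -0.28 to -0.17. Scale, centring and direction of that table are therefore settled.

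Each array had 62976 spots, of which 3671 control spots and any spot marked non-uniform were left out. Spots of 1 probe were averaged, which gave 56605 probes. The main values were log2 of the processed green signal minus the array's 75th percentile of it. A probe was kept if it was well above background on at least 6 arrays, the size of the smallest group, and 33454 probes were. The files hold no gene names, so accessions were matched without version to a RefSeq gene table of assembly GRCm38.p6, and no coordinates were used. That named 32994 probes by 22911 symbols and left 23611 without a symbol. Of several probes of a gene, the probe with the highest mean over all 19 arrays stood for it. Of 379 genes called between genotypes that had more than 1 kept probe, 283 had every probe in 1 direction. In all, 25603 genes were tested, 16104 of them with a symbol.

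The 75th percentile of the processed green signal ran from 664 to 1776 intensity units over arrays, and 51.4% to 59.4% of probes were well above background. Correlations between arrays, over genes, lay between 0.949 and 0.993. The number of arrays limits the precision. The arrays lay on 3 slides, each scanned in 1 session. Slide 1 held 6 WT and 2 APP/PS1 vehicle arrays, slide 2 held 5 APP/PS1 vehicle and 3 UA arrays, and slide 3 held 3 UA arrays. Sex, which the labels do not give, was read from Xist and 4 Y-linked genes: 1 of 6 WT, 3 of 7 APP/PS1 vehicle and 1 of 6 UA arrays were female.

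Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) and data.table (version 1.17.8). A single fit over all 19 arrays gave the 3 differences between groups. Tests were 2-sided with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Gene lists for cell types and pathways were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. Counts adjusted over the list alone are given beside those over all genes tested. Each list's mean level per array was also compared by an exact permutation test. Where a gene was not well above background on any array of a group, the fold is a lower bound, the bright group's mean against the lowest signal of probes well above background.

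The test was checked on simulated data with 25487 genes and 50 changed genes per fold size. For APP/PS1 vehicle against WT, 58% of genes changed 1.5-fold and 82% of those changed 2-fold were recovered. For UA against APP/PS1 vehicle these shares were 52% and 68%, and for UA against WT 50% and 64%. False calls made up 1.71%, 4.19% and 4.97% of the calls. The simulated noise was independent for each gene and array, with no structure shared between genes such as that of slide or sex. These shares are therefore not error rates for the real arrays.

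Groups, lists, tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, App and Prnp, and the 10 largest rises and 10 largest falls past the threshold among genes with a plain symbol, without Xist, Tsix and Y-linked genes. It also took up to 4 passing members of each list by p, and the 2 members of smallest p in each list called by camera. With fewer than 10 calls it took all of them and the 5 rises and 5 falls of smallest unadjusted p. Some genes the rule named are not reported here.

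The lists covered plaque-associated (DAM) and homeostatic microglia, complement and phagocytic receptors, reactive astrocytes, interferon response and antigen presentation, cytokines and inflammasome, mitophagy and autophagy, lysosome and TFEB, oxidative phosphorylation, mitochondrial biogenesis, synapse, immediate early genes, tau and amyloid processing, aryl hydrocarbon receptor and NRF2 targets, neurogenesis, circadian clock, glucocorticoid response, and heat and cold shock. Cell type lists covered neurons, interneurons, pyramidal and granule cells, astrocytes, oligodendrocytes and their precursors, vessels, meninges, choroid plexus and ependyma, blood, and neighbouring thalamus, striatum and cortex.

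Alternatives were other background corrections and scalings, the deposited score table, other filters and probe rules, slide or replicate number as a block, fits within a slide or of 2 groups, array weights, a variance trend, sex as a covariate and leaving out each array. The files hold no mean spot signal, so the normexp alternative (offset 50) took the median signal. Added after seeing the data were the background-subtracted signal before dye normalization, male arrays only, the choroid plexus level as a covariate, slide with sex, leaving out both doubted arrays, and the permutation test of list means.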

Results

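Transcript levels were measured in the hippocampus of 8-month-old mice in 3 groups: wild-type (WT) littermates on vehicle (n = 6), APP/PS1 mice on vehicle (n = 7) and APP/PS1 mice on urolithin A (UA, n = 6). APP/PS1 vehicle against WT shows how the amyloid model differed from its littermates. UA against APP/PS1 vehicle shows what differed with the compound, given for the last 2 months, and UA against WT what still set treated APP/PS1 mice apart. Levels are log2 of the array signal relative to each array's 75th percentile, and differences are given with the SE of the limma fit. Of all probes, 51.4% to 59.4% were well above background on each array.

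The transgenes of this strain are expressed from a mouse prion protein vector, and the brightest probe of the prion gene Prnp set APP/PS1 arrays apart from WT arrays. At that probe Prnp signal was 3.18-fold higher in APP/PS1 vehicle than in WT (log2 difference 1.67, SE 0.10, limma adjusted p = 1.43e-08), at 8.61 ± 0.16 (SD, n = 7) against 6.94 ± 0.12 (n = 6). In UA arrays it was at 8.60 ± 0.23 (n = 6), 3.15-fold above WT (adjusted p = 4.71e-08). The lowest APP/PS1 array, at 8.32, lay above the highest WT array, at 7.05, so no array went against its genotype label. App fell 1.32-fold between WT and APP/PS1 vehicle at its brightest probe (log2 difference -0.40, SE 0.10, limma adjusted p = 0.0291). The second probe of each gene, tested on its own, did not pass: for App the difference was 0.52 (SE 0.22, adjusted p = 0.170) and for Prnp -0.14 (SE 0.11, adjusted p = 0.460). Where each probe lies relative to the transgene sequence is not known from the files, so App checks nothing here. For the same reason the Prnp rise at 1 probe cannot be read as a rise of the endogenous gene.

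In APP/PS1 vehicle hippocampus, 5 of the 10 largest rises over WT among genes with a plain symbol were in members of the plaque-associated microglia list: Cst7, Itgax, Ccl4, Ccl6 and Cd52. Genes without one were left out of the ranking, 1 of which rose by 4.38. Cst7, which encodes a cathepsin inhibitor of microglia near plaques, was 72.5-fold higher (log2 difference 6.18, SE 0.25, limma adjusted p = 3.63e-11), and was well above background on 2 of 6 WT arrays and all 7 APP/PS1 vehicle arrays. Itgax, an integrin subunit, rose 8.65-fold (log2 difference 3.11, SE 0.17, adjusted p = 6.61e-09). The chemokine genes Ccl4 and Ccl6 rose 7.02-fold and 5.20-fold (Ccl4 was well above background on 2 of 6 WT arrays, so its fold, like that of Cst7, rests partly on signal near background), and Cd52, a leukocyte surface glycoprotein, 4.03-fold. The survival gene Bcl2a1d rose 3.65-fold. Bcl2a1c, not well above background on any WT array, was at least 2.58-fold higher. The interferon-induced genes Cxcl10 and Ifi27l2a rose 3.30-fold and 3.21-fold. Cxcr6, a chemokine receptor, passed the test (adjusted p = 0.0192) but was not well above background on any WT array and on 4 of 7 vehicle arrays, so no fold is given.

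**Figure D1:**
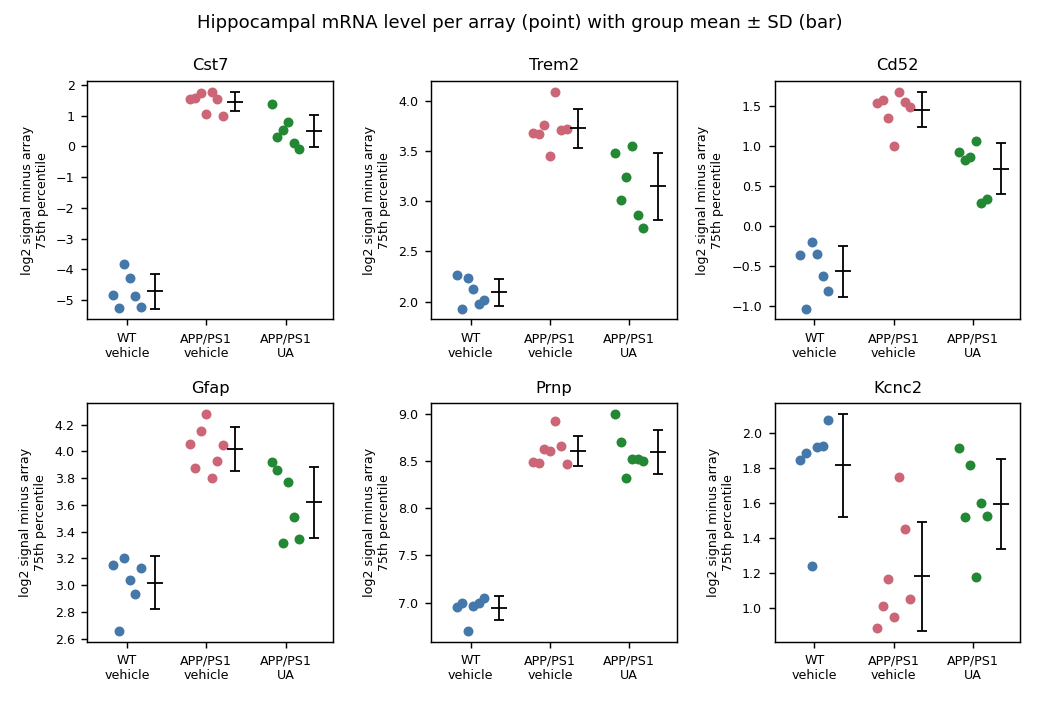
Level of 6 genes on each array (points, log2 signal minus the array's 75th percentile) with the group mean and SD (bars) for WT vehicle, APP/PS1 vehicle and APP/PS1 UA mice. Cst7, Cd52, Trem2 and Gfap were higher in APP/PS1 vehicle than in WT, as was Prnp at its brightest probe, and Kcnc2 was lower. That Prnp probe was at 8.61 in vehicle and 8.60 in UA arrays.

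The microglial lists rose together in APP/PS1 vehicle mice. Of 25 measured genes of plaque-associated microglia, 17 rose and none fell (19 rose when adjusted over the list alone), with a median log2 difference of 0.80. Of 19 complement and phagocytic receptor genes 15 rose (15 over the list alone), with a median of 0.88. Among them were the C1q subunit gene C1qa (1.82-fold, SE 0.087 on the log2 scale), the Fc receptor genes Fcer1g (1.95-fold) and Fcgr3 (1.85-fold), and Ly86 (2.27-fold). Of 13 homeostatic microglia genes 7 rose (9 over the list alone), including Gpr34 (1.74-fold), Fcrls (1.58-fold) and Csf1r (1.47-fold), the receptor that microglia need to survive. Camera called all 3 lists higher (adjusted p = 2.49e-24, 4.76e-23 and 3.74e-09 in that order). With an estimated correlation the adjusted p was 0.00449 and 0.0145 for the first pair and 0.0590 for homeostatic microglia. The mean level of the plaque-associated list was 2.04 ± 0.14 in APP/PS1 vehicle arrays (n = 7) and 0.89 ± 0.16 in WT arrays (n = 6), a difference of 1.15 (exact permutation p = 0.000583, the smallest these groups allow, adjusted 0.00622, 7 of 7 arrays above the WT mean). Within slide 1 that difference was 1.20, and the complement list's was 0.72 both within slide 1 and over all arrays. In male arrays (n = 4 and 5) the plaque-associated list differed by 1.07. Its exact permutation p of 0.00794 was the smallest those groups allow, but the adjusted p was 0.0847, so it did not pass there.

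Some astrocyte, antigen presentation and lysosome genes also rose in APP/PS1 vehicle mice, and camera called their lists higher only at its preset correlation. Of 16 reactive astrocyte genes 4 rose (7 over the list alone). Gfap, the astrocyte intermediate filament, rose from a level of 3.02 ± 0.20 (n = 6) to 4.02 ± 0.16 (n = 7, limma adjusted p = 5.68e-05), Aspg 1.99-fold and Osmr, the oncostatin M receptor gene, 1.65-fold. Of 26 interferon and antigen presentation genes 12 rose (23 over the list alone) and all 26 differences were above 0. The list's mean difference over all arrays was 0.74, but in male arrays 0.47 (exact permutation p = 0.151). They included the immunoproteasome genes Psmb8 (1.73-fold) and Psmb9 (1.61-fold) and the class I light chain gene B2m (1.72-fold). Of 30 lysosome genes 5 rose (8 up and 1 down over the list alone), among them the cathepsin genes Ctss (2.07-fold) and Ctsh (1.99-fold) and the hydrolase genes Gusb (1.51-fold) and Hexa (1.25-fold). Of 9 general astrocyte markers 2 rose, the water channel gene Aqp4 (1.39-fold) and S100b (1.23-fold), and the same 2 over the list alone. Of 16 cytokine and inflammasome genes 2 rose (3 over the list alone), Tgfb1 (1.38-fold) and Pycard (1.45-fold), the inflammasome adapter gene. Camera called these 5 lists higher, with adjusted p = 2.50e-07 for reactive astrocytes, 1.13e-15 for interferon, 0.0239 for lysosome, 0.0183 for astrocytes and 0.0243 for cytokines. All 5 lost the call with an estimated correlation, where the adjusted p in that order was 0.0696, 0.188, 0.237, 0.198 and 0.0930. All 5 passed fry and the exact permutation test of list means, neither of which took slide into account. The exact permutation adjusted p was 0.0149, 0.0416, 0.0210, 0.0210 and 0.0140 in that order. In the fewer male arrays it ran from 0.109 to 0.371. None of the 5 passed there, but neither did any other list, the microglial lists included (adjusted p = 0.0847).

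Camera called synapse, neuron and interneuron lists lower in APP/PS1 vehicle mice, but not with an estimated correlation (adjusted p = 0.237, 0.246 and 0.247), and most of their members did not pass. With slide as a block none of the genes below kept its call, while the synapse list's mean difference was -0.21 within slide 1 and over all arrays. Of 37 synapse genes 5 fell and none rose (13 fell and 1 rose over the list alone), with a median log2 difference of -0.22. They included the postsynaptic adhesion genes Nlgn2 (1.34-fold, log2 difference -0.42, SE 0.093, limma adjusted p = 0.0174) and Nlgn1 (1.33-fold), the vesicle gene Vamp2 (1.27-fold) and the glutamate receptor gene Gria3 (1.23-fold). Of 8 general neuron markers and 9 interneuron markers none passed over all genes (2 and 3 fell over the list alone). Sst, the somatostatin gene, differed by -0.62 (SE 0.19, adjusted p = 0.0601), Gad1 by -0.42 (SE 0.12, adjusted p = 0.0570), Syt1 by -0.29 (SE 0.092, adjusted p = 0.0742) and Snap25 by -0.29 (SE 0.10, adjusted p = 0.0962). Of 30 tau and amyloid processing genes 3 fell (4 over the list alone): Mme (1.47-fold), which encodes the amyloid-degrading protease neprilysin, the beta-secretase gene Bace1 (1.22-fold) and the Cdk5 activator gene Cdk5r1 (1.22-fold). Camera called the synapse (adjusted p = 1.70e-05), neuron (0.0107), interneuron (0.0107) and tau and amyloid (0.0104) lists lower. With an estimated correlation the tau and amyloid list did not hold either (adjusted p = 0.236). By exact permutation of list means, which took no account of slide, these 4 lists passed (adjusted p = 0.0332, 0.0416, 0.0416 and 0.0354 in that order). In the fewer male arrays, where no list passed, the exact permutation adjusted p of these 4 ran from 0.109 to 0.169. The synapse list's mean difference there was -0.20.

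Mitochondrial, immediate early and circadian lists were also lower by camera at its preset correlation, with few or no members past the test. Of 39 mitophagy and autophagy genes 1 fell (1 over the list alone), Gabarapl1 (1.29-fold, log2 difference -0.37, SE 0.081, limma adjusted p = 0.0179), and Usp15, which opposes mitophagy, differed by -0.21 (SE 0.064, adjusted p = 0.0643). Of 35 genes of mitochondrial biogenesis, dynamics and stress 1 fell (0 over the list alone), the chaperone gene Hspd1 (1.21-fold), and Asns differed by -0.32 (adjusted p = 0.0624). None of 22 immediate early and 16 circadian genes passed (0 and 0 over the list alone). Fosb differed by -0.45 (adjusted p = 0.0920), Fosl2 by -0.46 (0.195), Nr1d2 by -0.30 (0.112) and Tef by -0.20 (0.0834). Camera called the mitophagy (adjusted p = 0.0312), mitochondrial (0.0104), immediate early (0.0341) and circadian (0.0183) lists lower. The adjusted p with an estimated correlation was, in the same order, 0.347, 0.198, 0.577 and 0.432. By exact permutation of list means the adjusted p was 0.111, 0.0210, 0.377 and 0.279. Only the mitochondrial list passed that test, and in the fewer male arrays, where no list passed, it did not (exact permutation adjusted p = 0.141).

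**Figure D2:**
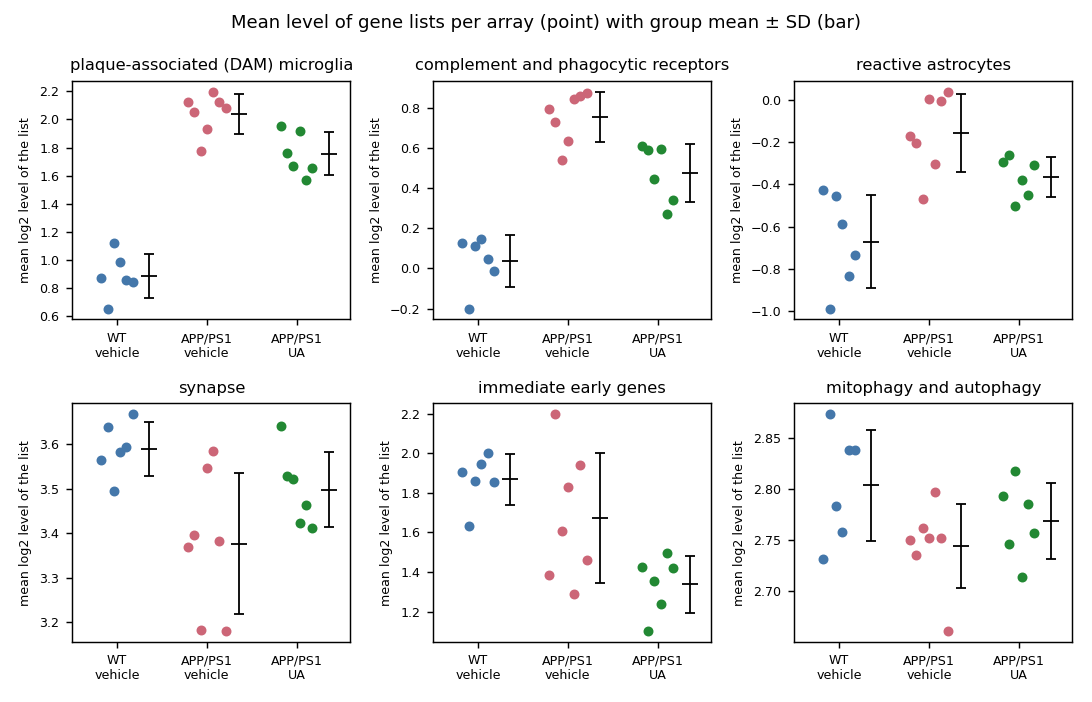
Mean level of the members of 6 gene lists on each array (points, log2) with the group mean and SD (bars) for WT vehicle, APP/PS1 vehicle and APP/PS1 UA mice. The plaque-associated microglia list averaged 0.89 in WT, 2.04 in APP/PS1 vehicle and 1.76 in UA arrays, and the mitophagy list 2.80, 2.74 and 2.77.

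The other 16 lists had no call between genotypes (camera adjusted p from 0.0596 to 0.995). In these, 3 of 52 oxidative phosphorylation genes fell (Atp5b 1.27-fold, Ndufa10 1.27-fold and Atp5a1 1.23-fold), as did 3 of 19 heat and cold shock genes (Hsp90aa1 1.37-fold, Hspa8 1.27-fold and Hsp90ab1 1.26-fold). The aryl hydrocarbon receptor gene Ahr fell 1.37-fold and the neurogenic factor gene Neurod1 1.39-fold. No member passed in the glucocorticoid, pyramidal, granule cell, oligodendrocyte, oligodendrocyte precursor, vessel, meninges, choroid plexus, blood, thalamus, striatum and cortex lists. For the neurogenesis and granule cell lists the sign of the median, the mean or the test differed. The 10 largest falls among genes with a plain symbol were those of Lgr5 (2.12-fold), a Wnt pathway receptor gene, the morphogen gene Shh (1.85-fold), Sfrp2 (1.74-fold), Tmem169 (1.67-fold), Rgs16 (1.58-fold), Lama3 (1.56-fold), the interneuron potassium channel gene Kcnc2 (1.56-fold), Acvr2a (1.54-fold), Trim66 (1.54-fold) and Zfp9 (1.51-fold).

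In total, limma called 1296 of 25603 genes between APP/PS1 vehicle and WT, 687 higher and 609 lower. Of these 88 were higher and 2 lower by over 2-fold, and 6141 genes had an unadjusted p under 0.05 where chance gives 1280. The share of calls that were higher was 53.0%, but 64.4% with the percentile taken over probes detected on all arrays, 71.3% with z-scores and 40.2% with the deposited values, so the balance of rises and falls is not settled. It was 82.2% with no filter on dim probes. With slide as a block 76 genes passed, 65 higher and 11 lower (71 of them among the 1296), and of the falls named above Zfp9 alone kept its call, though the differences were not smaller throughout (Kcnc2 -0.87 in place of -0.64). Within slide 1 22 passed, all higher (20 among the 1296), with sex as a covariate 1964 and in male arrays 245. Leaving out WT replicate 2, 4, 5 or 6 gave 448, 695, 550 and 389 calls, APP/PS1 vehicle replicate 1, 2, 6 or 7 gave 575, 823, 719 and 746, and WT replicate 3 or APP/PS1 vehicle replicate 5 gave 2262 and 2035. Camera called 16 lists, 8 higher and 8 lower. All 16 kept their sign within slide 1, where the circadian, cytokine, immediate early, lysosome and mitophagy lists lost their call, as they did in male arrays. Mean differences within slide 1 were near those over all arrays for cytokine (0.15 and 0.18), lysosome (0.14 and 0.15) and mitophagy lists (-0.060 and -0.059), and smaller for circadian (-0.066 and -0.15) and immediate early genes (-0.078 and -0.19). Choroid plexus transcripts had a mean level of 0.053 in WT and 1.31 in APP/PS1 vehicle arrays, and ran from -3.66 to 3.54 over all arrays.

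**Figure D3:**
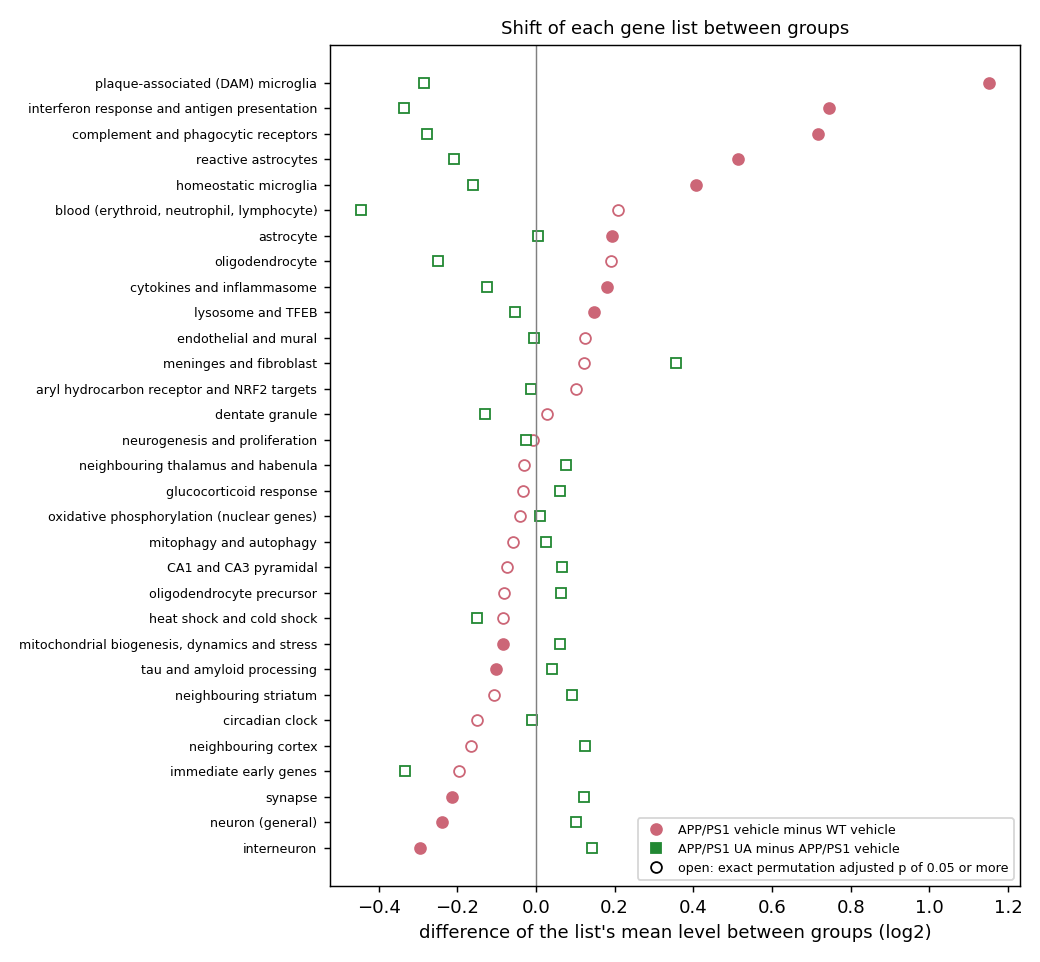
Difference of each gene list's mean level, choroid plexus left out, between groups (log2, horizontal axis) for APP/PS1 vehicle minus WT vehicle (circles) and APP/PS1 UA minus APP/PS1 vehicle (squares), with open symbols for an exact permutation adjusted p of 0.05 or more. The plaque-associated microglia list stood at 1.15 for genotype and -0.28 for UA, and no list passed for UA.

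In UA-treated APP/PS1 mice camera called the complement, plaque-associated microglia and antigen presentation lists lower than in vehicle-treated ones, while no single gene passed the test. With an estimated correlation none of the 3 held (adjusted p = 0.458, 0.458 and 0.580), nor by exact permutation of list means (adjusted p = 0.112, 0.112 and 0.502). The complement and phagocytic receptor list had a median log2 difference of -0.37 over 19 genes (0 passed over all genes, 13 lower and 1 higher over the list alone). C1qb was at -0.54 (SE 0.10, limma adjusted p = 0.0853) and Fcer1g at -0.48 (SE 0.093, adjusted p = 0.0853), lower than the vehicle mean on 6 of 6 UA arrays. The higher member was the scavenger receptor gene Cd36, named after its values were seen (adjusted p = 0.282) and well above background on 1 of 7 vehicle and 5 of 6 UA arrays. The plaque-associated microglia list had a median of -0.25 over 25 genes (0 passed, 10 lower over the list alone). Cd52 stood at -0.74 (SE 0.15, adjusted p = 0.0934) and Trem2, a lipid-sensing receptor gene, at -0.58 (SE 0.13, adjusted p = 0.0946). All 26 interferon and antigen presentation differences were below 0 (median -0.35, 9 lower over the list alone), with Psmb8 at -0.42 (adjusted p = 0.141) and Psmb9 at -0.34 (adjusted p = 0.150). In male arrays that list's mean difference was -0.061, in place of -0.34 over all arrays, and its camera call was lost.

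Camera also called 5 further lists for UA, none of which held with an estimated correlation (adjusted p from 0.575 to 0.629). The homeostatic microglia list had a median of -0.21 over 13 genes (5 lower over the list alone), with Selplg at -0.36 (SE 0.090, limma adjusted p = 0.117) and Csf1r at -0.27 (adjusted p = 0.202). The reactive astrocyte list had a median of -0.23 over 16 genes (1 lower over the list alone), which was Gfap at -0.40 (SE 0.12, adjusted p = 0.149), with Osmr at -0.30 (adjusted p = 0.203). Immediate early genes, which neurons switch on with activity, had a median of -0.28 over 22 genes (0 over the list alone). Npas4 stood at -1.06 (SE 0.32, adjusted p = 0.162) and Arc at -0.90 (SE 0.29, adjusted p = 0.183), lower on 6 of 6 UA arrays. The synapse list was higher, with a median of 0.15 over 37 genes (0 over the list alone) and Nlgn1 at 0.39 (SE 0.11, adjusted p = 0.138). So was the list of mitochondrial biogenesis, dynamics and stress (median 0.065 over 35 genes, 0 over the list alone). In it Ppargc1a, the coactivator gene of mitochondrial biogenesis, stood at 0.36 (SE 0.12, adjusted p = 0.178) and Polg, the mitochondrial DNA polymerase gene, at -0.19 (adjusted p = 0.208).

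Camera called these 8 lists, 6 lower and 2 higher: complement (adjusted p = 3.51e-09), interferon (5.16e-07), plaque-associated microglia (4.51e-06), immediate early genes (0.00210), synapse (0.00267), homeostatic microglia (0.00570), reactive astrocytes (0.0124) and mitochondrial biogenesis (0.0407). With an estimated correlation none held, and the adjusted p in the same order was 0.458, 0.580, 0.458, 0.575, 0.629, 0.575, 0.575 and 0.575. By the exact permutation test of list means none passed either, the smallest adjusted p being 0.112. The plaque-associated list averaged 1.76 ± 0.15 in UA arrays against 2.04 ± 0.14 in vehicle arrays, a difference of -0.28 (exact permutation p = 0.00874, adjusted 0.112, lower on 6 of 6). The complement list differed by -0.28 (exact permutation p = 0.00641, adjusted 0.112, lower on 6 of 6). Within slide 2, with 3 UA and 5 vehicle arrays, these differences were -0.23 and -0.20 (exact permutation p = 0.125 and 0.0893). In male arrays the interferon list's mean difference was -0.061 in place of -0.34 (exact permutation p = 0.794), and its call was lost (camera adjusted p = 0.0983). The calls of reactive astrocytes (-0.17 in place of -0.21) and mitochondrial biogenesis (0.049 in place of 0.062, camera adjusted p = 0.221), whose differences moved less, were lost too. Within slide 2 homeostatic microglia lost the call (-0.097 in place of -0.16, adjusted p = 0.116), and so did mitochondrial biogenesis with a difference of 0.066 in place of 0.062 (adjusted p = 0.0696).

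The other 24 lists had no call for UA (camera adjusted p from 0.144 to 0.834), and 0 of their members passed over all genes. The mitophagy and autophagy list had a median log2 difference of 0.032 over 39 genes, with 28 above 0 (camera adjusted p = 0.162). The 1 member past the threshold over the list alone was Atg9a, named after its values were seen, lower by -0.89 (SE 0.23, limma adjusted p = 0.117 over all genes). Medians were -0.033 for lysosome, -0.0023 for oxidative phosphorylation, 0.029 for tau and amyloid processing and -0.0035 for aryl hydrocarbon receptor and NRF2 targets. The 1 member past the threshold over the list alone in the last of these was Ahr, named after its values were seen, at 0.35 (SE 0.093, adjusted p = 0.131). The sign of the median, the mean or the test differed for oxidative phosphorylation, aryl hydrocarbon receptor, neurogenesis and circadian lists. App stood at 0.15 (SE 0.099, adjusted p = 0.473) and Prnp at -0.015 (SE 0.10, adjusted p = 0.960).

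Limma called 0 of 25603 genes between UA and APP/PS1 vehicle, with a smallest adjusted p of 0.0853. At an unadjusted p under 0.05 there were 3958 genes, 1497 higher and 2461 lower, where chance gives 1280. Lowest in p were Rbm22, Sntg2, Dek, Zfp9 and Med26 among the higher (log2 differences 0.38, 0.63, 0.33, 0.38 and 0.31) and AI506816, Cd300c2, H2-Q10, Kcp and Cyba among the lower (-0.52, -0.49, -0.62, -0.42 and -0.51). None of them passed (adjusted p from 0.0853 to 0.0941). Array weights and a robust variance trend also gave 0 calls, and so did slide as a block and the fit within slide 2. The count was 2 with normexp and quantile normalization and 10 without APP/PS1 vehicle replicate 4. With the choroid plexus level as a covariate, added after seeing the data, it was 65 (24 higher, 41 lower).

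Against WT, 7 of 25 plaque-associated microglia genes rose in UA-treated APP/PS1 mice. Cst7 was 37.5-fold higher (log2 difference 5.23, SE 0.26, limma adjusted p = 1.34e-09), Itgax 5.59-fold (adjusted p = 3.93e-07), Ccl4 4.55-fold, Ccl6 3.66-fold, Cd52 2.42-fold, Bcl2a1d 2.36-fold, the lysozyme gene Lyz1 2.28-fold and Trem2 2.08-fold. Bcl2a1c was at least 1.49-fold higher. The folds of Cst7 and Ccl4 rest partly on WT signal near background, as above. The only gene that fell was the crystallin gene Crybb2 (1.68-fold, log2 difference -0.75, SE 0.14, adjusted p = 0.0426).

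By list, 7 of 25 plaque-associated microglia genes rose (16 over the list alone, median 0.49), as did 2 of 19 complement genes (15 over the list alone, median 0.42), Ly86 (1.75-fold) and Laptm5 (1.60-fold). Of homeostatic microglia 0 of 13 passed (9 over the list alone, median 0.30), Aif1 standing at 0.51 (SE 0.13, limma adjusted p = 0.211). Of reactive astrocyte genes 1 of 16 rose (3 over the list alone, median 0.31), Aspg (1.64-fold), and Gfap stood at 0.60 (SE 0.12, adjusted p = 0.0619). Of 9 astrocyte markers 0 passed (4 over the list alone), with Aqp4 at 0.44 (adjusted p = 0.0821) and Sox9 at 0.32 (adjusted p = 0.404). All 22 immediate early genes were below WT (0 passed, 12 lower over the list alone, median -0.44). Fos stood at -1.45 (SE 0.35, adjusted p = 0.147) and Nr4a1 at -1.02 (SE 0.29, adjusted p = 0.291), each lower on 6 of 6 UA arrays. Camera called these 6 lists (adjusted p = 7.81e-33, 1.04e-23, 7.14e-09, 2.95e-06, 3.08e-04 and 1.84e-11 in that order). With an estimated correlation the adjusted p was 0.000908, 0.0128, 0.0419, 0.0803, 0.0419 and 0.0419, so reactive astrocytes lost their call. Plaque-associated, complement and immediate early list means differed by 0.87, 0.44 and -0.53 (exact permutation p = 0.00216, the smallest these groups allow, adjusted 0.0231 for each). Those of homeostatic microglia, reactive astrocytes and astrocyte markers did not pass (exact permutation adjusted p = 0.0693 for each).

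Camera called 8 further lists against WT, and all 8 lost the call with an estimated correlation (adjusted p from 0.307 to 0.549). Higher were interferon (median 0.32, adjusted p = 7.14e-09), lysosome (0.026, 0.0173), meninges (0.49, 3.08e-04), choroid plexus (1.53, 0.00199) and vessels (0.12, 0.0479), and lower were heat and cold shock (-0.26, 1.40e-05), circadian (-0.13, 0.00349) and synapse (-0.12, 0.0189). Over all genes 0 members of these lists passed. Over the list alone 6 lysosome genes passed as higher and 1 as lower, and 5 heat shock genes as lower. In the order above, the adjusted p with an estimated correlation was 0.381, 0.307, 0.381, 0.549, 0.474, 0.353, 0.381 and 0.540. Members of smallest p were Ifi27l2a (1.09) and Psmb9 (0.34), Ctsh (0.64) and Ctss (0.73), Col1a1 (0.24) and Slc22a6 (0.71), Aqp1 (1.53) and Prlr (1.54), Tagln (0.36) and Ly6c1 (0.14), Hsp90ab1 (-0.35) and Hsp90aa1 (-0.32), Per1 (-0.43) and Tef (-0.19), and Grin1 (-0.29) and Ntrk2 (0.23). The smallest of their limma adjusted p values was 0.0522, for Ctsh. The other 18 lists had no call (camera adjusted p from 0.0574 to 0.992), and for neurogenesis, glucocorticoid, pyramidal, blood and striatum lists the sign of the median, the mean or the test differed. App stood at -0.25 (SE 0.10, adjusted p = 0.501). Choroid plexus transcripts had a mean level of 1.37 in UA and 0.053 in WT arrays.

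Limma called 24 genes between UA and WT, 23 higher and 1 lower, 13 of the higher by over 2-fold. At an unadjusted p under 0.05 there were 2261 genes, 1072 higher and 1189 lower, where chance gives 1280. UA and WT arrays never shared a slide, and with slide as a block 4 genes passed, all of them among the 24. In male arrays 9 passed, all among the 24, and 144 with array weights. With slide as a block the circadian, lysosome, meninges and synapse lists lost their call, and 13 of the 14 called lists kept the sign of their mean difference.

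All 23 genes raised in UA against WT were also raised in APP/PS1 vehicle against WT. Both comparisons use the same WT arrays. Independent lists of these sizes would share 0.617 genes, and 50 simulations of unchanged groups against the WT arrays gave 0. The former leaves out the shared arrays and the latter any effect, so neither tests whether sharing them produced the overlap. With the WT arrays split so that each comparison used other ones, a median of 5 genes (3 to 7 over 20 splits) were called in both, where the UA lists held 3 to 9.

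On the genes called between genotypes, the UA arrays lay between the other groups. The 687 genes higher in APP/PS1 vehicle averaged -0.23 ± 0.10 in WT, 0.43 ± 0.087 in APP/PS1 vehicle and 0.11 ± 0.056 in UA arrays, a UA difference from vehicle of -0.31 (exact permutation p = 0.000583, the smallest these groups allow, lower on 6 of 6). For 654 of the 687 the UA mean fell between those of the other groups. The 609 lower genes averaged 2.28 ± 0.093, 1.91 ± 0.095 and 2.12 ± 0.071, a UA difference of 0.21 (exact permutation p = 0.00350), and 591 lay between. These genes were chosen on the same vehicle arrays, which pulls the UA values toward WT with no effect of treatment. With the vehicle arrays split, so that genes were chosen on some and compared on others, the difference averaged -0.37 for higher genes. The UA mean was below vehicle in 70 of 70 combinations of split and role (median exact permutation p = 0.0119). For lower genes the difference averaged 0.16 (median exact permutation p = 0.274), above vehicle in all 37 combinations that had 5 or more such genes. The combinations reuse the same arrays, so they are not replicates and the median p values do not test the averages. Splitting the vehicle arrays also leaves differences between slides in place. With slide as a block genes were called anew, 76 in place of 1296, and 85.5% of them were higher. On those higher genes the UA difference was -0.39, and on the few lower ones -0.0080. The 687 and 609 genes themselves were not compared under the block.

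**Figure D4:**
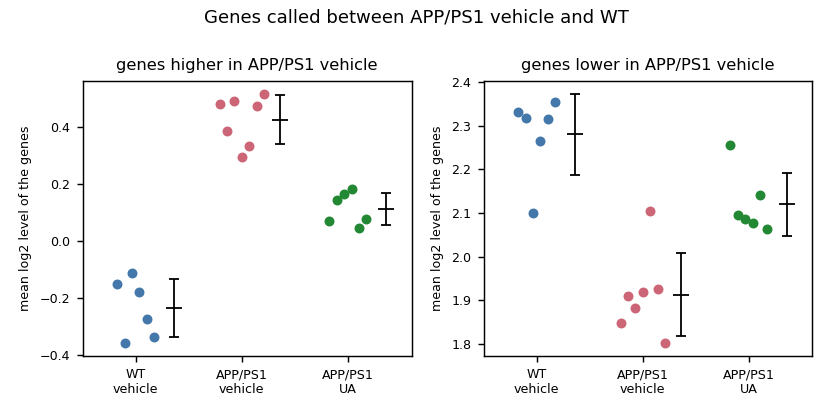
Mean level per array (points, log2) of the genes called higher (left) and lower (right) in APP/PS1 vehicle than in WT, with group mean and SD (bars). The genes were chosen on the WT and vehicle arrays shown, and the UA arrays averaged 0.11 and 2.12.

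Across genes, which are not independent replicates, the genotype and UA differences had a covariance of -0.0576 and a correlation of -0.662. Unchanged groups simulated with the same shared vehicle arrays gave a mean covariance of -0.0229 (SD 0.0155) and a correlation of -0.451, and 38 of 1000 simulations had a covariance as low as observed. With the vehicle arrays split the covariance averaged -0.0304 and the correlation -0.283. It was -0.0778 without APP/PS1 vehicle replicate 3, and -0.0205 with normexp and quantile normalization.

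**Figure D5:**
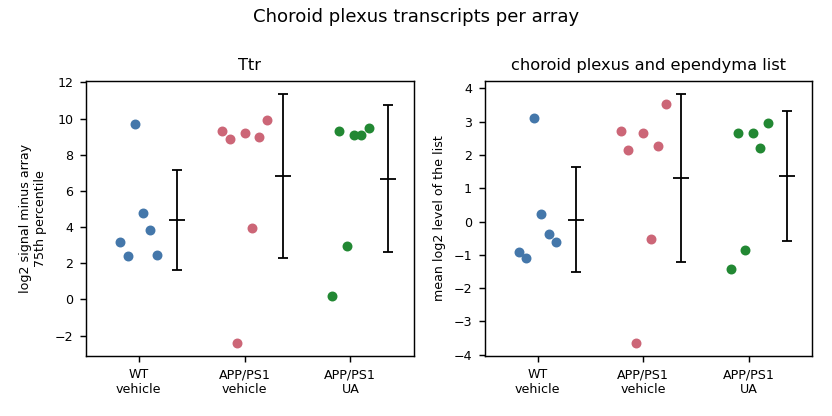
Level of the choroid plexus gene Ttr (left, log2 signal minus the array's 75th percentile) and mean level of the choroid plexus and ependyma list (right, log2) on each array (points), with group mean and SD (bars). The list mean ran from -3.66 to 3.54 and the spread within groups exceeded the difference between their means.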

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

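The tests of the microglial and slide patterns, those of carried-along tissue and of group for choroid plexus, and the rules that left 2 explanations open were chosen after the results were seen. The array flags below came from a fixed rule, a gap to the nearest other array of the same group that was large beside the group's range, and chance flags about 1 in 20 groups. It flagged 32 of 414 groups, 26 of 306 for genes, 5 of 96 for list means and 1 of 12 for array measures.

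Lists of plaque-associated microglia and complement genes were lower in UA than in vehicle arrays, by -0.28 over their 44 genes (exact permutation p = 0.00641). The vehicle group held more females, but in male arrays alone the difference was -0.24 (exact permutation p = 0.0397), which sex balance as the whole cause does not account for. Dye normalization against the red channel does not account for it either, since the background-subtracted green signal gave -0.28 (exact permutation p = 0.00583). Within slide 2 it was -0.21 (exact permutation p = 0.107), too few arrays to exclude a part played by the slide. The male arrays lay on 3 slides, so sex and slide were not held constant together. Male vehicle arrays had means of 1.55 and 1.48 on slide 1 and 1.24 and 1.37 on slide 2. Male UA arrays of slide 2 had 1.25 and 1.14. Sex and slide acting together are therefore not excluded. A lower level of microglial transcripts with UA remains possible, and fewer microglia cannot be told from lower expression per cell.

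Choroid plexus transcripts spread widely over arrays of every group, with list means from -3.66 to 3.54 and Ttr over a 5254-fold range. Choroid plexus or ependymal tissue carried along in some dissections fits, since list members moved together within groups (median correlation over pairs 0.944). A hybridisation fault was predicted to give a red to green SD ratio of at least 0.5, and the ratio, 0.555, met that. It was nevertheless left open by a check chosen afterwards. Separate probes of the same gene agreed within groups (median correlation 0.981 over 4 genes, lowest 0.888). Aqp1, the member brightest in red, ranged over 4.24 in green and 0.371 in red, the smallest red range of the list. Red signal varied widely for other members, for Ttr from -6.77 to 3.36 and for Clic6 from -6.66 to 1.17. Aqp1 therefore does not speak against a fault. Genotype or treatment could not be told from chance (permutation p = 0.467), with a largest difference between group means of 1.31.

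Far fewer genes were called between APP/PS1 vehicle and WT with slide as a block, 76 in place of 1296. Genes were picked with slide 2 vehicle arrays at a limma unadjusted p under 0.001, on average 102.05 of them as higher. Those differed by 1.04 in the slide 1 vehicle arrays against other WT arrays, beside 1.23 where picked. Slide alone does not account for these strong rises as a set, but weaker rises were not picked, so for them slide was not tested. For genes picked as lower the values were -0.064 and -0.79, which met the prediction for slide as the cause. That was left open by a rule added after the value was seen, since on average 3.55 such genes were picked, and it is not evidence against slide. Loss of arrays may be a further cause, as 2 of the 5 slide 2 vehicle arrays gave a median of 123 calls without a block (35 to 928 over 10 pairs), beside 76. The 2 slide 1 vehicle arrays gave 227 without a block, so loss of arrays need not be the whole cause. They share slide 1 with all WT arrays, so those 227 passed with no slide difference in the comparison. The block fit rests on the same slide 1 difference, so 227 and 76 differ only through the spread estimated.

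Single arrays stood apart for microglial and astrocyte genes as follows. Among WT arrays, replicate 1 was low for Ccl6 (-2.24) and Ly86 (1.69), and replicate 2 for Bcl2a1c (-6.43). Among APP/PS1 vehicle arrays, replicate 3 was low for Ctss (5.13) and replicate 5 high for Fcrls (0.81). UA replicate 1 was low for S100b (4.95).

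For neuronal and synaptic genes, WT replicate 3 was low for Nlgn1 (0.95), Nlgn2 (5.20), Kcnc2 (1.24), Mme (-2.56) and Ahr (-0.16). APP/PS1 vehicle replicate 7 was low for Sst (5.80) and the interneuron list (3.04), and replicate 5 high for Bace1 (3.06) and Tmem169 (-2.80). UA replicate 2 was low for Gad1 (3.71) and UA replicate 3 high for Cdk5r1 (5.79). UA replicate 1 was high for the tau and amyloid list (2.83).

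Of the transgene-related genes, App was high in WT replicate 1 (7.82), and Prnp low in WT replicate 3 (6.70) and high in APP/PS1 vehicle replicate 5 (8.93). WT replicate 3 was high for the choroid plexus genes Aqp1 (2.87) and Prlr (2.19) and for their list (3.11), and held the most flags of any array, 9. APP/PS1 vehicle replicate 3 was high for Hspa8 (7.55), AI506816 (0.33) and the oxidative phosphorylation list (6.49), and replicate 6 low for Rbm22 (-2.05). UA replicate 4 was high for Ly6c1 (3.92) and the neurogenesis list (-0.34), and UA replicate 1 for Asns (5.55).

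WT replicate 5 had 172 non-uniform spots where the other WT arrays had 1 to 33. The red channel, used in no comparison, held signal on every array: at least 55.1% of its probes were well above background, and the labels used here name no sample for it.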

How the results depend on the processing

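Background-subtracted signal, male arrays, the choroid plexus covariate, slide with sex, leaving out the 2 doubted arrays and the permutation test of list means were chosen after seeing the data; the other alternatives were fixed before. Genes called between APP/PS1 vehicle and WT, 1296 as reported, were 279 with z-scores, 804 with deposited values, 353 with no filter on dim probes, 76 with slide as a block (76 with sex added), 2251 with slide as a random block, 22 within slide 1, 436 in a fit of the 2 groups alone, 3908 with array weights, 1964 with sex, 637 on background-subtracted signal (69.4% higher), 245 in males and 713 without the doubted arrays. Leaving out each array gave 389 to 2262. The random block's estimated correlation within slides was -0.0447, here and for UA against WT. With a negative value that block makes no allowance for differences between slides, so its counts do not speak against slide. UA against vehicle, 0 as reported, gave 2 with normexp and 65 with the choroid covariate (0 to 10 leaving out each array). UA against WT, 24 as reported, gave 41 with probes well above background on all arrays, 38 with every probe tested, 4 with slide as a block (4 with sex added), 99 with slide as a random block, 144 with array weights and 9 in males (16 to 35 leaving out each array). Fewer arrays are compared within a slide and in males. A fit of 2 groups compares the same arrays, with the spread estimated without the third group. The tests made for slide as a block stand with the results above, and for the other changes the cause was not tested.

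The replicate numbers were not taken to pair the arrays, since 4 of 19 correlated best with an array of their own number in another group. Between APP/PS1 vehicle and UA, 4 of 6 pairs of the same number correlated over 0.1 (median 0.285). Between WT and each of these groups 2 of 6 did (medians -0.089 and -0.026), so a partial pairing is not excluded. With the replicate block the counts were 338, 0 and 12. No fit within a slide was possible for UA against WT, whose arrays shared none.

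Gene lists called, 16 between genotypes, were 9 with z-scores, 2 with an estimated correlation, 14 with fry and 13 by exact permutation (13 to 18 leaving out each array). For UA against vehicle the 8 became 0 with an estimated correlation, 3 with fry and 0 by exact permutation (6 to 9). For UA against WT the 14 became 5, 6 and 3 in that order (12 to 15). The Prnp difference kept its call throughout (1.62 to 1.69 leaving out each array). The covariance of -0.0576 was -0.0205 with normexp, -0.0416 with probes well above background on all arrays, -0.0786 without the doubted arrays and -0.0304 with vehicle arrays split (-0.0778 to -0.0429 leaving out each array). For the UA difference on higher and lower genes, each alternative called its genes anew, so its values cover differing sets of genes. On higher genes this difference kept its sign and call throughout (-0.35 to -0.28 leaving out each array). On lower genes, 0.21 as reported, it was 0.16 with vehicle arrays split (0.17 to 0.25 leaving out each array). It was -0.0080 with slide as a block and -0.055 with sex added, where 76 genes were called in all, higher and lower together. The cause was not tested.

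For named genes, 2269 of 2862 genotype values under alternatives kept sign and call, 558 lost the call, 34 gained it and 1 turned sign; for UA against vehicle 1082 of 1107 kept and 12 turned, and for UA against WT 1341 of 1475 kept and 5 turned. Prnp between UA and vehicle turned from -0.015 to 0.11 (normexp), 0.083 (quantile), 0.0012 (probe mean), 0.012 (slide block and within slide 2), 0.00099 (array weights), 0.043 (sex), 0.062 (slide with sex), 0.038 (without vehicle replicate 5), 0.041 (without UA replicate 3) and 0.0031 (without UA replicate 6). App with probes averaged turned to 0.059 between genotypes, -0.041 for UA against vehicle and 0.019 for UA against WT. Against WT with slide as a block, Col1a1 turned to -0.066 (-0.10 with sex) and Slc22a6 to -0.20 (-0.072 with sex). The cause was not tested. Signal over background limits genes that WT arrays barely hold: Bcl2a1c and Cxcr6 were well above background on 0 of 6 WT arrays and Cst7 and Ccl4 on 2.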

Other observations

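The aryl hydrocarbon receptor, which binds indoles and other aromatic ligands, and the NRF2 targets were a list of 20 measured genes that camera did not call in any comparison. Between genotypes 1 member fell, Ahr itself, and 1 was higher and 1 lower over the list alone, the higher being the oxidative stress gene Osgin1 at 0.75, named after its values were seen (list-alone adjusted p = 0.0459 by limma). In UA against vehicle Ahr was at 0.35 and against WT at -0.10. Heat and cold shock genes had 5 members lower against WT in the UA group over the list alone. These included the chaperone genes Hspa1a (-0.57) and Dnajb1 (-0.55), named after their values were seen. All 8 general neuron markers were above vehicle in UA arrays (camera adjusted p = 0.162), and all 10 oligodendrocyte markers below (camera adjusted p = 0.184).

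The chance splits were planned before the results were seen, and the choice to look at choroid plexus levels in them came afterwards. Each comparison was repeated over 100 splits of its arrays into groups of the same sizes, the real one included. Between APP/PS1 vehicle and WT, 1 split, the real one, reached 1296 genes (highest other 4), and for UA against WT 1 reached 24 (highest other 2), so chance without regard to slide can be excluded for these counts. Nearly all other splits mixed slides more than the real groups did, so slide is not excluded, and with slide as a block the counts were 76 and 4. For UA against vehicle the real count was 0, which all 100 splits reach by construction, so this count tests nothing. The highest other split called 1491 genes, which points to a structure of the samples. Its groups had mean choroid plexus levels of -0.21 and 2.67. Another split with levels of -0.22 and 2.67 called 0 genes but had 3233 at an unadjusted p under 0.05, where the median of the other splits was 999. Over all 19 arrays the choroid plexus list mean followed the main axis of variation between arrays, the first principal component. Their correlation was 0.934 in size, and that axis held 31.6% of the variance. Whether choroid plexus content produced the 1491 calls is left open. For lists, 7 splits reached the real 16 between genotypes (highest other 20), 40 reached the 8 for UA against vehicle (highest other 16) and 12 reached the 14 for UA against WT (highest other 19), so chance cannot be excluded for any count of lists. At an unadjusted p under 0.05, 2 of 100 splits, the real one included, reached the 3958 genes of UA against vehicle, the highest other holding 7045. So few splits reach that number by chance, but the split above it shows that groups unrelated to treatment can exceed it.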
